A study of Mus musculus with 10 samples.

How the data were processed

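The samples were visceral adipose tissue from 10 mice, 5 after sham surgery and 5 with orthotopic KPC tumours, and the group and number of each mouse were taken from the labels. All sample titles end in gwat, read here as gonadal white adipose tissue. Per the labels' protocols, the tissue was flash frozen, RNA was extracted with a Qiagen RNeasy Plus Mini kit and libraries were made at Genewiz following Illumina protocols. The authors deposited a table of gene counts normalized by them and a table of TPM, which gives each gene its length-corrected share of all transcripts. Per the submitters' processing notes, Salmon, DESeq, DESeq2 and the mouse build mm10 were used by the authors, and versions, the annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads from overlapping genes and their antisense partners cannot be told apart, and Salmon divides reads between near-identical copies by an estimate. All 20 sample columns of the 2 tables matched 1 sample each by name.

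The normalized counts are handled here as a signal that is never negative, since the deposited values are not whole reads divided by a factor. For the best step found per sample, 30.9% to 47.3% of values up to 30 came out within 0.05 of a whole number, so whole reads were not recovered and no count model was run. The ratio of normalized count to TPM within a gene was constant across samples up to 1 factor per sample. Its median SD was 0.00041 (log2) over the 10131 genes above 100 normalized counts in every sample. Sample factors ran from -0.11 to 0.15 on the log2 scale. Both deposited tables therefore carry one quantification in different scalings. The table of normalized counts held 16667 genes, 81 of them at 0 in all samples, and 29242 genes were listed with TPM.

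Depth was read from the values. The totals of normalized counts were 20941200 to 24449900 per sample, and the steps between low values gave an estimate of 15700000 to 23930000 assigned reads, which the authors' scaling makes approximate. The median SE of a log2 difference over the tested genes was 0.172. Labels give separate mice as samples, so p-values reflect the spread between 5 mice per group and not counting error alone.

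Genes were tested with limma 3.58.1 in R 4.3.3, with a variance trend, on log2(normalized count + 1), for the 14203 genes with a mean of at least 10, and p-values were adjusted by Benjamini and Hochberg over these genes with a threshold of 0.05. Gene lists of cell types, pathways and quality signs were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives except those called later. Of these lists, 44 had at least 3 tested members. Pancreatic acinar, epididymis and testis, and sex-linked lists had fewer and were not tested. Each list was tested by camera in limma with a preset correlation of 0.01 and again with an estimated one, by fry, and by an exact two-sided permutation test of the mean log2 value per mouse, over all assignments of 5 of 10 mice. Each was adjusted over the 44 lists. Intervals of list differences invert that permutation test and cover 95%. A list is said here to have risen only where the exact test passed. List symbols were matched to the tables, with Folr4, Atp5f1 and Cyr61 taken under their current symbols Izumo1r, Atp5pb and Ccn1, and Muc16, Ahsp, Atp5o, Gbp5, Ddit3 and Xist were not analysed here.

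The rule for named genes took up to 8 genes with the largest change in each direction among those that passed, with a mean normalized count of at least 50, a gene symbol that is no model name and no overlap between groups. It added up to 4 members of each described list with the smallest unadjusted p and members of the other direction, and a fixed set of genes the question is about, among them Il33, Il4, Retnla, Adipoq, Lep, Pnpla2 and Ucp1. All 8 genes that passed met this rule, and the 1 called lower and some list members are not reported here. Csf2rb, Acta1, Prss2, Cpa1, Epcam and Ddx3y were named after their values were seen. Coordinates are from GENCODE vM21 on GRCm38, matched by Ensembl gene identifier.

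The gene and list tests were tested on simulated data drawn for the comparison of KPC against sham with 14203 genes. Over 5 simulations, 359 of 500 genes changed by a log2 of 1 (71.8%) and 461 of 500 changed by a log2 of 2 (92.2%) were called, and 40 of 862 calls (4.64%) were wrong. These changed genes were drawn outside all lists, among genes with a mean normalized count of at least 50. The shares recovered therefore do not cover lower genes. A list changed by 0.6 log2 reached the smallest exact p in all 5 simulations. Of 215 unchanged lists, 16 had an exact p under 0.05 before adjustment and 0 were called by camera. Genes were drawn independently of each other here, while estimated correlations within the real lists reached 0.951. The simulations therefore cannot give the error of camera, or the power of the list tests, for correlated lists.

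Alternatives planned before the data were examined were other pseudocounts, filters, scalings and sample weights, the TPM table, a robust fit, the mouse number and the title number as a block, removal of a gene length trend, other list tests and leaving out each mouse in turn. Added after the data were seen were the mean of the skeletal muscle list as a covariate, leaving out KPC mouse 1 with sham mouse 5, leaving out sham mice 3 to 5, the type 2 list without Ccl8, and the test of the alternatively activated against the macrophage list with shared members left out of both.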

Results

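RNA was sequenced from the visceral adipose tissue of 10 wild-type C57BL/6 mice aged 10 weeks, 5 after sham surgery and 5 carrying orthotopic KPC pancreatic tumours. KPC names a mouse model of pancreatic ductal adenocarcinoma, and orthotopic means that the tumour was placed in the pancreas. The series asks whether type 2 immunity, the arm of adipose immunity that runs through interleukin 33, group 2 innate lymphoid cells, eosinophils and alternatively activated macrophages, is kept while fat is lost in mice with cancer. The table of normalized counts held 16667 genes, of which 14203 had a mean of at least 10 and were tested. Each library summed to between 20941200 (KPC mouse 1) and 24449900 (sham mouse 1) normalized counts, and the steps between low values put the assigned reads at an estimated 15700000 (KPC mouse 3) to 23930000 (sham mouse 5). Levels below are mean ± SD in TPM, a length-corrected share of all transcripts, over 5 mice per group, log2 differences and folds are on the log2(normalized count + 1) scale, and the value after ± beside a log2 difference is its SE. Where a pair of levels is given, the sham value stands first and the KPC value after it.

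The tissue was rich in adipocyte transcripts in both groups. Adipoq, the gene of the fat hormone adiponectin, stood at 4290.0 ± 559 TPM in sham and 4264 ± 673 TPM in KPC mice. Mitochondrially encoded genes took 26.3% to 33.3% of TPM in 9 libraries and 15.7% in KPC mouse 1. That library also had the lowest correlation with the others, with a median of 0.908 on the log2 scale, where the other 9 libraries had medians of 0.939 to 0.959. The first principal component carried 28.9% of the variance, and KPC mouse 1 lay at 91.07 on it, beyond the next library at 27.6.

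Between tumour-bearing and sham mice, 7 genes rose and 1 was called lower by limma. Mt2, which encodes the metal-binding protein metallothionein 2, stood at 93.0 ± 22.5 TPM in sham and 752 ± 562 TPM in KPC mice, a rise of 7.07-fold (95% interval 3.87 to 12.9). Cebpd, a transcription factor induced by inflammatory cytokines and glucocorticoids, stood at 8.52 ± 1.81 against 32.9 ± 8.68 TPM, a rise of 3.90-fold (95% interval 2.77 to 5.49). Csf2rb2, a receptor chain for interleukin 3, stood at 5.54 ± 1.08 against 13 ± 0.849 TPM, and Osmr, a receptor chain for oncostatin M, at 11.1 ± 1.46 against 18.3 ± 2.76 TPM. Ifi205 and Ifi207, interferon-inducible genes of the p200 family, stood at 46.7 ± 5.74 against 119.6 ± 35.7 TPM and at 9.52 ± 1.49 against 24.0 ± 7.36 TPM. Cyb561, a membrane cytochrome that passes electrons to ascorbate, stood at 4.46 ± 0.287 against 9.93 ± 2.43 TPM.

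For these 7 genes all 5 KPC mice lay above all 5 sham mice. The log2 differences were 2.82 ± 0.40 for Mt2, 1.96 ± 0.22 for Cebpd, 1.35 ± 0.18 for Ifi205, 1.33 ± 0.18 for Ifi207, 1.28 ± 0.12 for Csf2rb2, 1.15 ± 0.15 for Cyb561 and 0.74 ± 0.10 for Osmr. Their adjusted p-values by limma ranged from 0.00301 for Csf2rb2 to 0.0299 for Mt2. Csf2rb2 is a near copy of Csf2rb, Mt2 of Mt1, and Ifi205 and Ifi207 belong to a cluster of related genes, so reads divided between copies leave these levels uncertain. Csf2rb itself stood at 7.23 TPM in sham and 12.8 TPM in KPC mice on average.

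On the GRCm38 (mm10) assembly with the GENCODE vM21 annotation, the 7 genes that rose are protein-coding. Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) and Cebpd (ENSMUSG00000071637, chromosome 16, 15887286 to 15891031) lie on the plus strand. The others lie on the minus strand: Ifi205 (ENSMUSG00000054203, chromosome 1, 174011998 to 174031810), Ifi207 (ENSMUSG00000073490, chromosome 1, 173723427 to 173741747), Csf2rb2 (ENSMUSG00000071714, chromosome 15, 78282507 to 78305721), Cyb561 (ENSMUSG00000019590, chromosome 11, 105933702 to 105953336) and Osmr (ENSMUSG00000022146, chromosome 15, 6813577 to 6874969).

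With these calls included, 1920 genes had an unadjusted limma p under 0.05, 1081 higher and 839 lower in KPC, where 710 would be reached by chance at that threshold. Among 100 divisions of the 10 mice into groups of 5, the real one included, the highest other reached 1717 genes, and it exchanged 1 mouse of each group. At an adjusted p under 0.1 the counts were 69 higher and 13 lower. For 390 genes every KPC mouse lay above every sham mouse and for 182 every KPC mouse lay below, together 4.03% of the genes tested, where chance gives 0.794%. The count of calls depended on single libraries. Without KPC mice 1 to 5 in turn it was 66, 13, 6, 1 and 4 higher and 4, 1, 2, 1 and 1 lower, and without sham mice 1 to 5 in turn 2, 2, 2, 1 and 3 higher and 1 lower each time. On TPM with a pseudocount of 1, calls split into 2 higher and 0 lower in place of 7 and 1, and with the skeletal muscle list as a covariate, chosen after the data were seen, 0 were called higher and 1 lower. With the first number of each sample title as a block, 3 were called higher and 1 lower, Cebpd and Csf2rb2 among the 3, and the labels do not say what that number marks.

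**Figure D1:**
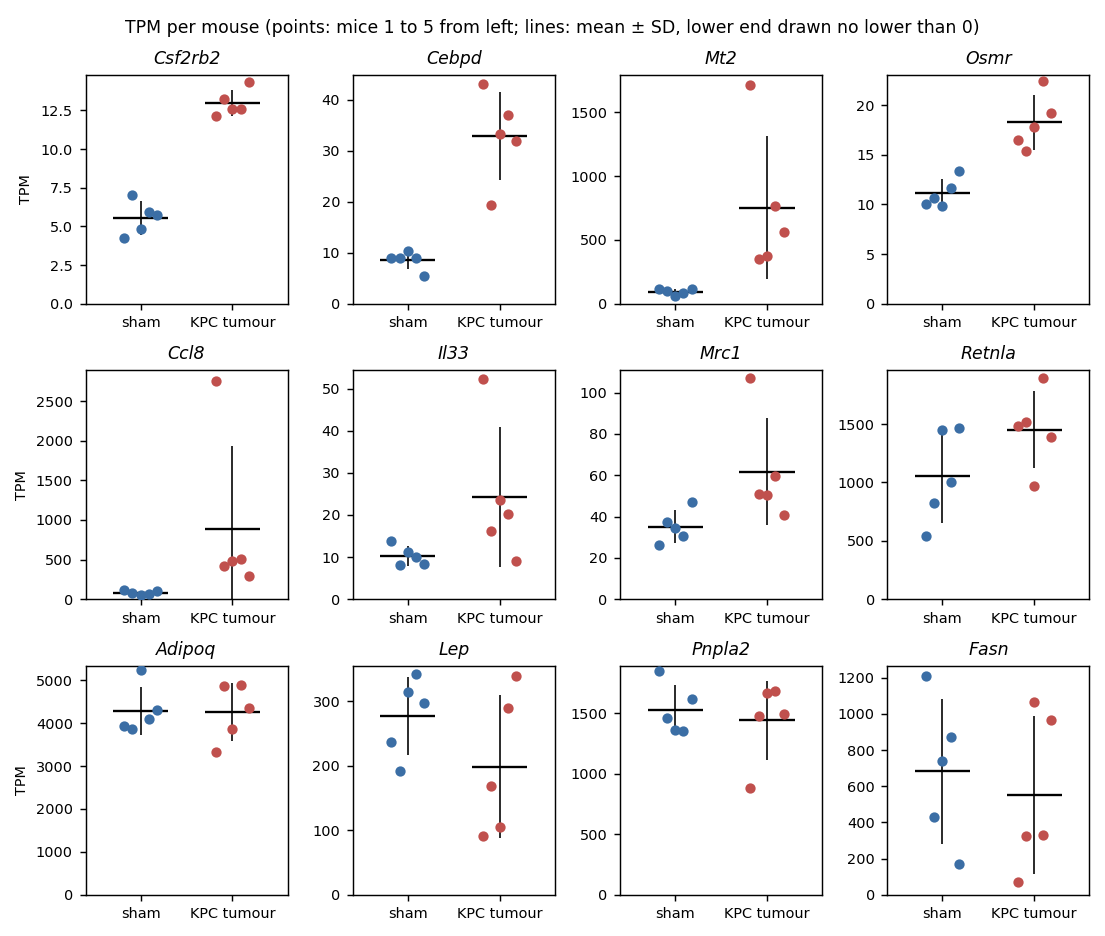
TPM of 12 genes in each mouse, with the sham group at the left of each panel and the KPC tumour group at the right; each point is 1 mouse, horizontal lines are means over 5 mice and vertical lines are ± 1 SD. The 5 KPC mice lie above the 5 sham mice for Csf2rb2, Cebpd, Mt2, Osmr and Ccl8, and the groups overlap for Il33, Mrc1, Retnla, Adipoq, Lep, Pnpla2 and Fasn.

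Type 2 genes as a group were higher in tumour-bearing mice. The list of type 2 cytokines, receptors and chemokines rose by a mean log2 difference of 0.51 (95% interval 0.20 to 0.87) over its 13 measured members, and all 5 KPC mice lay above all 5 sham mice. Camera called the list too, where adjusted p = 0.258 with an estimated correlation, and without Ccl8, a step chosen after the data were seen, the difference was 0.30 and the exact test did not pass. Its member with the largest difference was the chemokine gene Ccl8, at 83.8 ± 24.1 TPM in sham and 891 ± 1044 TPM in KPC mice (426 ± 95.3 TPM without KPC mouse 1), and Ccl11, the eosinophil attractant eotaxin, stood at 71.5 ± 11.8 TPM in sham and 97.3 ± 10.4 TPM in KPC mice. Il33, the alarmin that activates group 2 innate lymphoid cells, stood at 10.3 ± 2.33 TPM in sham and 24.2 ± 16.5 TPM in KPC mice, and Il13ra1, a receptor chain for interleukins 4 and 13, at 6.75 ± 1.05 TPM in sham and 11.6 ± 4.83 TPM in KPC mice. The interleukin 33 receptor gene Il1rl1 stood at 1.93 ± 0.484 against 2.25 ± 0.734 TPM. Gata3, the transcription factor of type 2 lymphocytes, stood at 0.387 ± 0.134 against 0.532 ± 0.0920 TPM. None of the members named here passed over all genes tested. The limma adjusted p was 0.07949 for Ccl8, 0.1965 for Ccl11, 0.2301 for Il13ra1 and 0.3003 for Il33. The limma adjusted p was 0.698 for Il1rl1 and 0.450 for Gata3. For Il33 the groups overlapped.

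Macrophage genes lay higher in the same mice. Relative to the sham mean, KPC mice 1 to 5 had type 2 list values of 1.01, 0.44, 0.22, 0.63 and 0.23 and macrophage values of 1.90, 0.71, 0.61, 0.88 and 0.35, where sham mice reached 0.07 and 0.36. Ccl8 and Ccl24 also stand in the list of alternatively activated macrophage genes. The exact permutation test of the type 2 list mean gave p = 0.00794, the smallest that the assignments of 5 mice against 5 can give, and an adjusted p of 0.0499 over 44 lists. Camera gave an adjusted p of 0.00242 for the same list. Of its members, 10 had a positive and 3 a negative difference, 0 passed over all genes tested, and 3 passed higher when adjusted over the list alone. The adjusted exact p was 0.116 without Ccl8, and without KPC mouse 1 the difference was 0.38 with an adjusted exact p of 0.0582. The call was also lost without any 1 sham mouse and under either other filter on low genes, and the adjusted exact p ranged from 0.0349 to 0.143 over the 21 alternatives that left enough mice for a pass. The cytokines themselves were at or below the level of testing: Il4 stood at 1.20 ± 0.629 against 1.42 ± 0.428 TPM, Il5 at 0 to 0.30 TPM in sham and 0 to 0.102 TPM in KPC libraries, and Il13 at 0 to 0.370 and 0 to 0.135 TPM.

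Eosinophil, group 2 innate lymphoid cell and regulatory T cell lists gave no call in either direction. Eosinophil genes differed by 0.21 (95% interval -0.47 to 0.95) over 6 members, with an adjusted exact p of 0.640 for the list. Within it, Ear2, an eosinophil-associated ribonuclease that macrophages also express, stood at 23.2 ± 6.97 against 48.7 ± 18.2 TPM, Siglecf, an eosinophil surface lectin, at 0 to 0.788 TPM in sham and 0.0810 to 0.534 TPM in KPC libraries, and Prg2, the granule major basic protein, at 0.576 to 1.68 and 0 to 1.67 TPM. Epx, eosinophil peroxidase, was listed at 0 in all 10 libraries. Adjusted over the eosinophil list alone, 1 member passed higher, Ear2, with no overlap between groups. The innate lymphoid cell and regulatory T cell lists had 0 such members. Genes of group 2 innate lymphoid cells differed by 0.21 (95% interval -0.07 to 0.52), with an adjusted exact p of 0.254 over 10 members. Genes of regulatory T cells differed by 0.29 (95% interval -0.10 to 0.73), with an adjusted exact p of 0.306 over 6 members. Without sham mouse 1 the eosinophil difference was -0.02 and the innate lymphoid cell difference 0.13. The eosinophil difference was 0.09 without KPC mouse 2, 0.32 without sham mouse 4 and 0.33 without KPC mouse 5, and without KPC mouse 1 the regulatory T cell difference was 0.18. Foxp3, the regulator of these T cells, was too low to test, at 0 to 0.0546 TPM in sham and 0.0183 to 0.172 TPM in KPC libraries, and Ikzf2, a further transcription factor there, stood at 1.12 ± 0.123 against 0.734 ± 0.194 TPM with a limma adjusted p of 0.255. The 3 intervals include 0 and leave room for differences either way, so the tests do not separate an equal level from a modest change.

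Alternatively activated macrophage genes rose by 0.87 (95% interval 0.35 to 1.56) over 18 members, 17 of them with a positive difference. The adjusted exact p of the list was 0.0499, the camera adjusted p 9.38e-09, and adjusted p = 0.258 with an estimated correlation. Macrophage genes in general lay higher too: with the 2 shared members, Mrc1 and Cd163, left out of both lists, the differences were 0.88 and 0.91. The difference between the lists, a test chosen after the data were seen, was -0.03 (95% interval -0.25 to 0.17, exact permutation p = 0.754), so the lists are not shown to differ. The C-type lectin genes Cd209a and Clec10a stood at 14.4 ± 3.33 against 25.2 ± 3.97 TPM and 58.3 ± 13.9 against 134 ± 57.9 TPM, and the scavenger receptor gene Cd163 at 21.2 ± 7.07 against 34.4 ± 9.29 TPM. Mrc1, the mannose receptor, stood at 35.1 ± 7.84 TPM in sham and 61.8 ± 26.1 TPM in KPC mice, and Retnla, a secreted product of macrophages exposed to interleukin 4, at 1055 ± 402 TPM in sham and 1453 ± 331 TPM in KPC mice. Arg1, arginase 1, stood at 0.717 ± 0.394 against 2.75 ± 4.09 TPM, or 0.923 TPM in KPC mice without KPC mouse 1, and the limma adjusted p was 0.236 for Mrc1, 0.339 for Retnla and 0.514 for Arg1. No member passed over all genes tested and 8 passed higher when adjusted over the list alone. The list also shares Ccl8 and Ccl24 with the type 2 list, Cd209a with dendritic cells, Chil3 with monocytes, Il10 with regulatory T cells and Lyve1 with lymphatic endothelial cells.

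**Figure D2:**
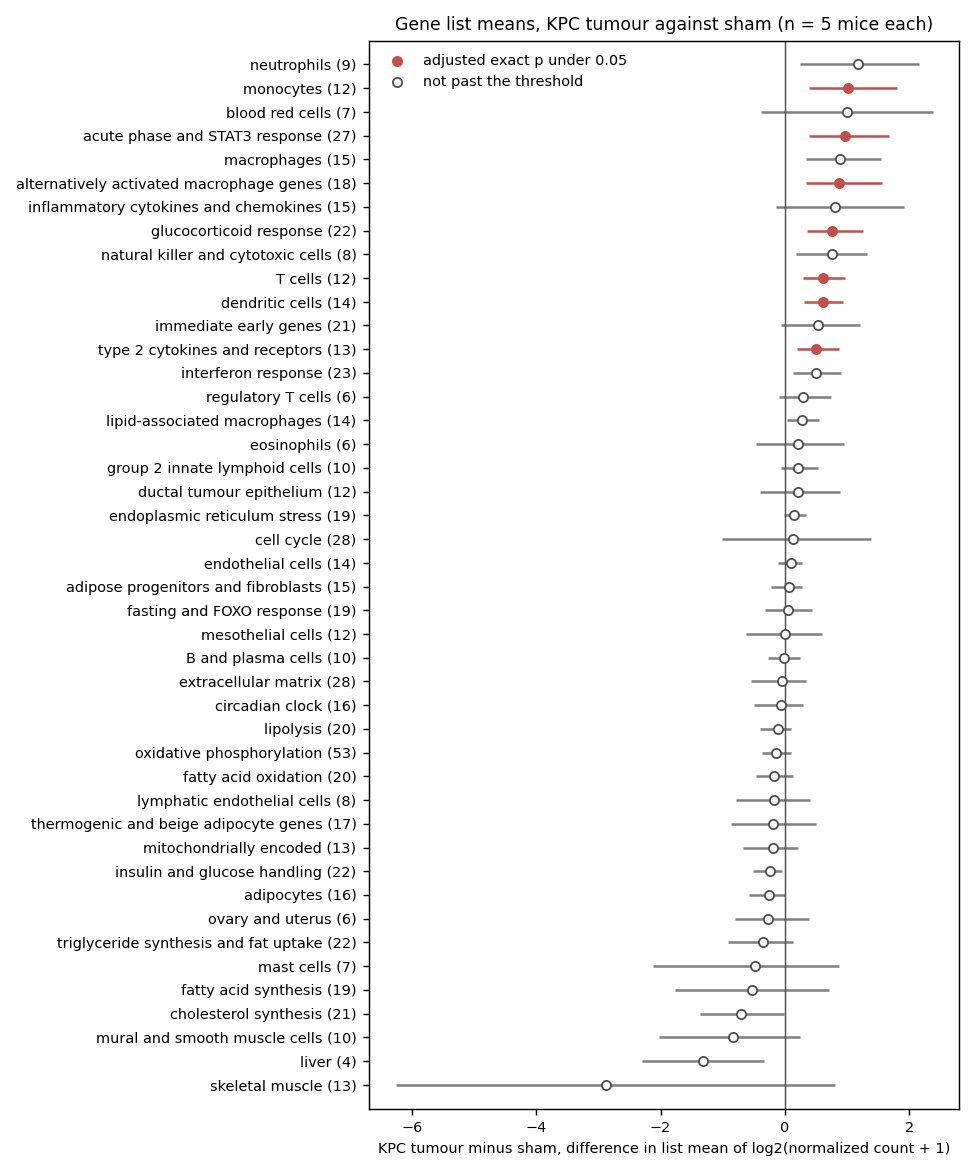
Difference in list mean between KPC tumour and sham mice for each of 44 gene lists, on the x axis in log2 units, with the list and its number of measured members on the y axis; points are differences between means of 5 mice, bars are 95% intervals from the inverted exact permutation test, and filled points passed an adjusted exact p of 0.05. The 7 filled lists all lie above 0, from 0.51 for type 2 cytokines and receptors to 1.01 for monocytes.

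Genes of monocytes, T cells and dendritic cells rose as well by the exact permutation test. Camera called these 3 lists too, and with an estimated correlation the adjusted p was 0.258 for monocytes, 0.224 for T cells and 0.224 for dendritic cells. Monocyte genes rose by 1.01 (95% interval 0.38 to 1.80) over 12 members, with Plac8, a gene of circulating monocytes, at 47.6 ± 15.6 against 212 ± 208 TPM and F10, coagulation factor X, at 0.243 ± 0.0447 against 1.50 ± 1.42 TPM. Their KPC means were 119 TPM and 0.868 TPM without KPC mouse 1. T cell genes rose by 0.62 (95% interval 0.29 to 0.96), and 12 of 12 members were positive, among them the coreceptor Cd8a at 0.346 ± 0.0835 against 0.657 ± 0.157 TPM, the adhesion receptor Cd2 at 2.13 ± 0.631 against 3.24 ± 0.590 TPM and the kinase Lck at 1.00 ± 0.376 against 1.63 ± 0.346 TPM. Dendritic cell genes rose by 0.61 (95% interval 0.30 to 0.94), with 14 of 14 members positive. Its members Clec9a, Flt3, Xcr1 and Siglech had log2 differences of 0.58, 0.32, 0.21 and 0.03, and none passed when adjusted over the list alone. Among the 4 members with the smallest p, the C-type lectin gene Cd209a is also in the alternatively activated list. The other 3 act in MHC class II antigen presentation. The class II regulator Ciita stood at 1.36 ± 0.302 against 3.12 ± 0.910 TPM. The class II chains H2-Eb1 and H2-Ab1 stood at 1.99 ± 0.60 against 5.30 ± 1.63 TPM and 290.3 ± 70.5 against 584 ± 179 TPM. Near copies among the H2 genes leave these levels uncertain. The adjusted exact p was 0.0499 for each of these 3 lists. Adjusted over the list alone, 4 monocyte, 0 T cell and 6 dendritic cell genes passed higher, and 0 of their members passed over all genes tested. Red cell genes were higher in some of the same mice: relative to the sham mean, their list lay at 2.36 in KPC mouse 1 and 1.74 in KPC mouse 2, which also had the highest monocyte values, 2.24 and 0.87, and T cell values, 0.89 and 0.83. KPC mice 3, 4 and 5 had red cell values of 0.39, 0.19 and 0.31, monocyte values of 0.76, 0.67 and 0.51 and T cell values of 0.33, 0.44 and 0.59, where sham mouse 1 had 0.97, 0.42 and 0.10.

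Macrophage and neutrophil genes lay higher without passing the exact test. Macrophage genes differed by 0.89 (95% interval 0.34 to 1.54) with an adjusted exact p of 0.0698; all 15 members were positive and 13 passed higher when adjusted over the list alone, among them Adgre1, the F4/80 antigen, at 17.8 ± 4.64 against 32.0 ± 10.0 TPM. Neutrophil genes differed by 1.17 (95% interval 0.24 to 2.16) with an adjusted exact p of 0.0806, and 2 of 9 passed when adjusted over the list alone, with Lcn2, lipocalin 2, at 2.41 ± 0.739 against 16.2 ± 14.1 TPM and Csf3r, the receptor for granulocyte colony-stimulating factor, at 1.33 ± 0.325 against 4.04 ± 3.16 TPM. The KPC means of these 2 genes were 10.6 TPM and 2.63 TPM without KPC mouse 1. Natural killer and cytotoxic genes differed by 0.75 (95% interval 0.18 to 1.32) with an adjusted exact p of 0.0806, and Klrb1c, the NK1.1 antigen, stood at 0.380 ± 0.131 against 0.984 ± 0.258 TPM. Lipid-associated macrophage genes differed by 0.27 (95% interval 0.03 to 0.55) with an adjusted exact p of 0.0998, and by 0.16 without KPC mouse 1. Camera called these 4 lists higher, and with an estimated correlation the adjusted p was 0.258 for macrophages, neutrophils and cytotoxic cells and 0.396 for lipid-associated macrophages.

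Genes of B cells, mast cells and red cells gave no call by the exact test. B and plasma cell genes differed by -0.02 (95% interval -0.27 to 0.25) with an adjusted exact p of 0.865, and Ms4a1, the CD20 antigen, stood at 0.741 ± 0.0640 against 0.575 ± 0.10 TPM. Mast cell genes differed by -0.48 (95% interval -2.12 to 0.87) with an adjusted exact p of 0.575. The mast cell chymase Cma1 was listed at 0 in KPC mice 3 and 5 and between 5.30 and 22 TPM in the other 8 libraries. Cma1 and Tpsb2 had the largest negative log2 differences, -2.50 and -1.09. Cpa3, Mcpt4 and Kit stood at -0.06, -0.02 and 0.01, Mrgprb1 at -0.32 and Fcer1a at 0.62. Among all genes tested, 139 had a library at 0 beside another at or above 100 normalized counts, and the cause was not tested. Haemoglobin and other red cell genes differed by 1.00 (95% interval -0.38 to 2.37) with an adjusted exact p of 0.273, and their Hbb-bs stood at 20700 TPM in KPC mouse 1 and 9180 TPM in KPC mouse 2, above the highest sham value of 5550 TPM. Camera called the red cell list higher, where adjusted p = 0.501 with an estimated correlation. With 1 mouse left out, the B cell difference ran from -0.10 (without sham mouse 5) to 0.03 (without sham mouse 1). Without KPC mouse 1 the red cell difference was 0.66, and the mast cell difference was -0.78 without KPC mouse 1, -0.75 without KPC mouse 4, -0.18 without KPC mouse 3 and -0.17 without KPC mouse 5. KPC mouse 1 gave the highest value of the leukocyte lists of monocytes, macrophages, neutrophils and T cells. Without it and sham mouse 5, a step chosen after the data were seen, 52 genes were called higher and 3 lower.

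Genes of the acute phase and the glucocorticoid response rose in tumour-bearing mice by the exact permutation test. With an estimated correlation the camera adjusted p was 0.236 for the acute phase and 0.258 for the glucocorticoid list. The acute phase and STAT3 list rose by 0.96 (95% interval 0.38 to 1.68) over 27 members, 24 of them positive; Cebpd and Osmr passed over all genes tested, and 15 passed higher when adjusted over the list alone. Stat3, the transcription factor activated by interleukin 6 family cytokines, stood at 41.4 ± 4.25 against 56.8 ± 7.41 TPM, its feedback inhibitor Socs3 at 8.48 ± 3.52 against 33.5 ± 34.6 TPM and the serine protease inhibitor Serpina3g at 2.67 ± 0.983 against 10.2 ± 4.56 TPM. Socs3 had a KPC mean of 18.4 TPM without KPC mouse 1. Relative to the sham mean, KPC mice 1 to 5 had acute phase values of 1.94, 0.71, 1.10, 0.63 and 0.41 beside neutrophil values of 2.53, 1.23, 1.32, 0.27 and 0.48 and macrophage values of 1.90, 0.71, 0.61, 0.88 and 0.35. The acute phase difference was 0.71 without KPC mouse 1. Lcn2 is a member of the neutrophil, acute phase, glucocorticoid and ductal tumour epithelium lists. Glucocorticoid response genes rose by 0.76 (95% interval 0.35 to 1.25), with 21 of 22 members positive, Mt2 past the test over all genes and 6 passing higher when adjusted over the list alone. Among them were Mt1, metallothionein 1, at 179.9 ± 25.5 against 658 ± 332 TPM, the kinase Sgk1 at 28.5 ± 4.28 against 62.0 ± 27.6 TPM and Nfkbia, an inhibitor of NF-kappa-B, at 56.3 ± 9.18 against 95.9 ± 25.2 TPM. The glucocorticoid list was highest in KPC mice 4 and 5, at least 1.12 above the sham mean, with 0.59, 0.30 and 0.48 in KPC mice 1 to 3. Metallothioneins and Nfkbia are also induced by cytokines and metals. Fkbp5, Tsc22d3, Per1, Zbtb16 and Klf9 lay higher by 1.19, 0.60, 0.50, 0.41 and 0.23 (log2) without passing when adjusted over the list alone. The adjusted exact p was 0.0499 for both lists.

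Interferon response genes lay higher by 0.50 (95% interval 0.13 to 0.89), with 21 of 23 members positive, 9 passing when adjusted over the list alone, and an adjusted exact p of 0.0698. The interferon-inducible GTPase genes Igtp and Gbp2 stood at 15.9 ± 0.885 against 23.5 ± 4.83 TPM and 40.5 ± 3.04 against 51.7 ± 3.75 TPM, and Oas2, a sensor of double-stranded RNA, at 2.52 ± 0.941 against 7.02 ± 4.71 TPM. The list was highest in KPC mouse 1, at 0.98 above the sham mean, with 0.26 to 0.47 in the other KPC mice. Inflammatory cytokine and chemokine genes differed by 0.81 (95% interval -0.15 to 1.91) with an adjusted exact p of 0.202. Il6 stood at 17.8 TPM in KPC mouse 1, was listed at 0 in 3 other KPC libraries and reached 1.10 TPM in sham. Tnf, at 0.157 ± 0.0775 against 0.183 ± 0.112 TPM, and Ifng, at 0 to 0.188 TPM in sham and 0 to 0.162 TPM in KPC libraries, were too low to test. Immediate early genes differed by 0.54 (95% interval -0.06 to 1.21) with an adjusted exact p of 0.202, and the stress-induced Atf3 stood at 6.11 ± 1.01 against 17.3 ± 7.22 TPM. Camera called these 3 lists higher, and with an estimated correlation the adjusted p was 0.278 for each. Genes of endoplasmic reticulum stress differed by 0.15 (95% interval -0.01 to 0.33), of the fasting and FOXO response by 0.06 (95% interval -0.31 to 0.43), and of the cell cycle by 0.13 (95% interval -1.01 to 1.38), none past the exact or the camera test. Without KPC mouse 1 the inflammatory difference was 0.38, the endoplasmic reticulum stress difference 0.08 and the cell cycle difference -0.28. The sign of the cell cycle difference also turned without sham mouse 2, at -0.03, and sham mouse 3, at -0.01, and the largest cell cycle difference was 0.38, without sham mouse 1. The fasting difference ran from -0.03 without sham mouse 1 to 0.12 without KPC mouse 1, and lay below 0 without KPC mouse 4 or 5 as well.

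Adipocyte genes lay slightly lower without passing the exact test. The adipocyte list differed by -0.25 (95% interval -0.57 to just below 0) with an adjusted exact p of 0.131, 10 of 16 members negative and 0 passing when adjusted over the list alone. Pparg, the master regulator of fat cell differentiation, stood at 91.3 ± 17.4 against 61.2 ± 15.8 TPM, Plin1, which coats lipid droplets, at 132 ± 12.9 against 95.4 ± 26.3 TPM, and Lpl, lipoprotein lipase, at 3453 ± 523 against 2063 ± 857 TPM. Lep, the gene of leptin, stood at 277 ± 61.1 against 199 ± 111 TPM, while Adipoq had a log2 difference of 0.02 ± 0.17. The limma adjusted p was 0.255 for Pparg, 0.279 for Plin1, 0.354 for Lpl, 0.428 for Lep and 0.973 for Adipoq. Camera called the list lower, where adjusted p = 0.543 with an estimated correlation. The list difference was -0.13 without KPC mouse 1.

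Genes of fat breakdown did not differ by more than the spread between mice. The lipolysis list differed by -0.12 (95% interval -0.41 to 0.10) with an adjusted exact p of 0.552. Pnpla2 and Lipe, which encode adipose triglyceride lipase and hormone-sensitive lipase, stood at 1526 ± 207 against 1440.0 ± 328 TPM and 697 ± 66.2 against 607 ± 139.8 TPM. In the same list, Npr3, the clearance receptor for natriuretic peptides, stood at 90.8 ± 29.6 against 40.9 ± 20.5 TPM. Thermogenic and beige adipocyte genes differed by -0.19 (95% interval -0.87 to 0.50) with an adjusted exact p of 0.629. Ucp1, the uncoupling protein of thermogenic fat, ranged from 0.0341 to 29.3 TPM among sham and from 0.624 to 13.4 TPM among KPC mice. Fatty acid oxidation genes differed by -0.17 (95% interval -0.46 to 0.12), and nuclear genes of oxidative phosphorylation by -0.14 (95% interval -0.36 to 0.09), with adjusted exact p-values of 0.349 and 0.349. Acadm, a dehydrogenase of fatty acid oxidation, stood at 255 ± 18.9 against 210.1 ± 30 TPM, and Uqcrc1, a subunit of respiratory complex III, at 232 ± 21.6 against 183 ± 25.2 TPM. Camera called both lists lower, and with an estimated correlation the adjusted p was 0.545 and 0.608. Without KPC mouse 1 the difference was -0.02 for lipolysis, -0.03 for thermogenic genes and -0.11 for fatty acid oxidation. Without sham mouse 1 it was -0.10 for fatty acid oxidation and -0.09 for oxidative phosphorylation, which stood at -0.08 without KPC mouse 4. The thermogenic difference was -0.04 and -0.12 without sham mice 2 and 4 and -0.34 without either sham mouse 5 or KPC mouse 4.

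Genes of lipid synthesis lay lower on average, with wide spread between mice. All 21 measured cholesterol synthesis genes had a negative difference, with a list mean of -0.71 (95% interval -1.37 to -0.01) and an adjusted exact p of 0.116. Hmgcs1, an early enzyme of the pathway, stood at 79.2 ± 21.8 against 52.3 ± 7.64 TPM. Fatty acid synthesis genes differed by -0.53 (95% interval -1.77 to 0.71) with an adjusted exact p of 0.552. Fasn, fatty acid synthase, stood at 683 ± 401 TPM in sham and 551 ± 437 TPM in KPC mice, and the desaturase gene Scd2 at 95.7 ± 34.7 against 50.4 ± 41.6 TPM, or 33.1 TPM in KPC mice without KPC mouse 3. Acsl5, which activates fatty acids, was the 1 member that passed higher when adjusted over the list alone, at 17.3 ± 1.17 against 21.2 ± 1.29 TPM. Triglyceride synthesis and fat uptake genes differed by -0.35 (95% interval -0.92 to 0.13) with an adjusted exact p of 0.335, and Angptl8, an insulin-induced inhibitor of lipoprotein lipase, stood at 33.9 ± 13 against 14.5 ± 6.36 TPM. Insulin and glucose handling genes differed by -0.25 (95% interval -0.51 to -0.05) with an adjusted exact p of 0.0806. There Pfkfb3, an activator of glycolysis, stood at 234 ± 60.7 against 128 ± 19.4 TPM and Irs1, the insulin receptor substrate, at 11.2 ± 2.38 against 7.08 ± 1.54 TPM, and both passed lower when adjusted over the list alone. Camera called the cholesterol, triglyceride and insulin lists lower, and with an estimated correlation the adjusted p was 0.278, 0.545 and 0.499. Without KPC mouse 1 the difference was -0.13 for fatty acid synthesis, -0.18 for triglyceride synthesis and -0.13 for insulin and glucose handling. Without KPC mouse 3 it was -0.84 for fatty acid synthesis, and without sham mouse 1 -0.22 for triglyceride synthesis.

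Stromal and vascular genes gave no list call by the exact test. Adipose progenitor and fibroblast genes differed by 0.06 (95% interval -0.22 to 0.28) with members going both ways: the adhesion molecule Icam1 stood at 13.1 ± 1.23 against 21.0 ± 3.26 TPM and the surface antigen Ly6a at 302 ± 41.2 against 500.5 ± 137 TPM, both higher when adjusted over the list alone, while the collagen gene Col15a1 stood at 214 ± 19.4 against 143 ± 48.7 TPM. The list difference was -0.004 without sham mouse 1 and 0.17 without sham mouse 5. Endothelial genes differed by 0.09 (95% interval -0.11 to 0.28), with von Willebrand factor, Vwf, at 30.9 ± 9.80 against 49.0 ± 10.8 TPM. Lymphatic endothelial genes differed by -0.17 (95% interval -0.79 to 0.40), extracellular matrix genes by -0.05 (95% interval -0.54 to 0.33) and circadian clock genes by -0.06 (95% interval -0.50 to 0.30). Leaving out 1 mouse turned the sign of these 3: the lymphatic difference was 0.01 without sham mouse 5, the matrix difference 0.11 without sham mouse 5 and 0.03 without KPC mouse 3, and the clock difference 0.06 without sham mouse 1. Over all such removals the lymphatic difference ran from -0.30 to 0.01, that of the matrix from -0.12 to 0.11, that of the clock from -0.16 to 0.06 and that of endothelial genes from 0.04 to 0.15. Within the matrix list the matrix protease Mmp3 stood at 10.2 ± 4.15 against 29.4 ± 18.1 TPM. Mural and smooth muscle genes differed by -0.84 (95% interval -2.02 to 0.24) with an adjusted exact p of 0.254, all 10 members negative, among them smooth muscle actin, Acta2, at 418 ± 377 against 184 ± 139 TPM, or 257 TPM in sham mice without sham mouse 5. Camera called this list lower, where adjusted p = 0.514 with an estimated correlation, and without sham mouse 5 the difference was -0.52.

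Markers of tissues outside fat gave no list call by the exact test, and skeletal muscle genes varied widely between mice. Skeletal muscle genes differed by -2.87 (95% interval -6.25 to 0.80) with an adjusted exact p of 0.209, and Acta1, skeletal muscle actin, stood at 140, 416 and 1270 TPM in sham mice 3, 4 and 5, at 37.0 and 24.8 TPM in sham mice 1 and 2 and at 20.1 to 90.4 TPM in KPC mice. Camera called the list lower, where adjusted p = 0.460 with an estimated correlation. Liver genes differed by -1.31 (95% interval -2.30 to -0.34) over 4 measured members with an adjusted exact p of 0.0698; albumin, Alb, stood at 15.4 ± 3.29 against 8.05 ± 2.55 TPM, and camera's adjusted p of 0.0241 became adjusted p = 0.323 with an estimated correlation. Mesothelial genes differed by 0.00 (95% interval -0.63 to 0.60), ovary and uterus genes by -0.27 (95% interval -0.80 to 0.39) and ductal tumour epithelium genes by 0.21 (95% interval -0.40 to 0.88), none past either test. Within the ductal list Lcn2 had the largest log2 difference, 2.40, and the median over the members was 0.01. With 1 mouse left out, the ovary and uterus difference ran from -0.51 (without sham mouse 1) to -0.13 (without sham mouse 4), the ductal difference from 0.04 (without KPC mouse 1) to 0.34 (without KPC mouse 5), and the mesothelial difference from -0.17 (without sham mouse 1) to 0.18 (without KPC mouse 5). The epithelial marker Epcam was listed at 0 in 9 libraries and at 0.119 TPM in KPC mouse 3, and the keratin Krt18, which mesothelium also expresses, stood at 6.83 ± 2.15 against 9.90 ± 3.81 TPM. The pancreatic acinar genes Prss2 and Cpa1 were at most 0.124 TPM in any library. The Y-linked Ddx3y was listed at 0 in all 10 libraries. However, 2 other members of the sex-linked list reached the mean of 10 normalized counts. Ddx3y therefore does not settle the sex of the mice, which the labels do not state. Mitochondrially encoded genes differed by -0.19 (95% interval -0.67 to 0.21), and camera's adjusted p of 0.0360 became adjusted p = 0.671 with an estimated correlation. Without KPC mouse 1 that difference was -0.03, and without sham mouse 1 it was -0.11.

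**Figure D3:**
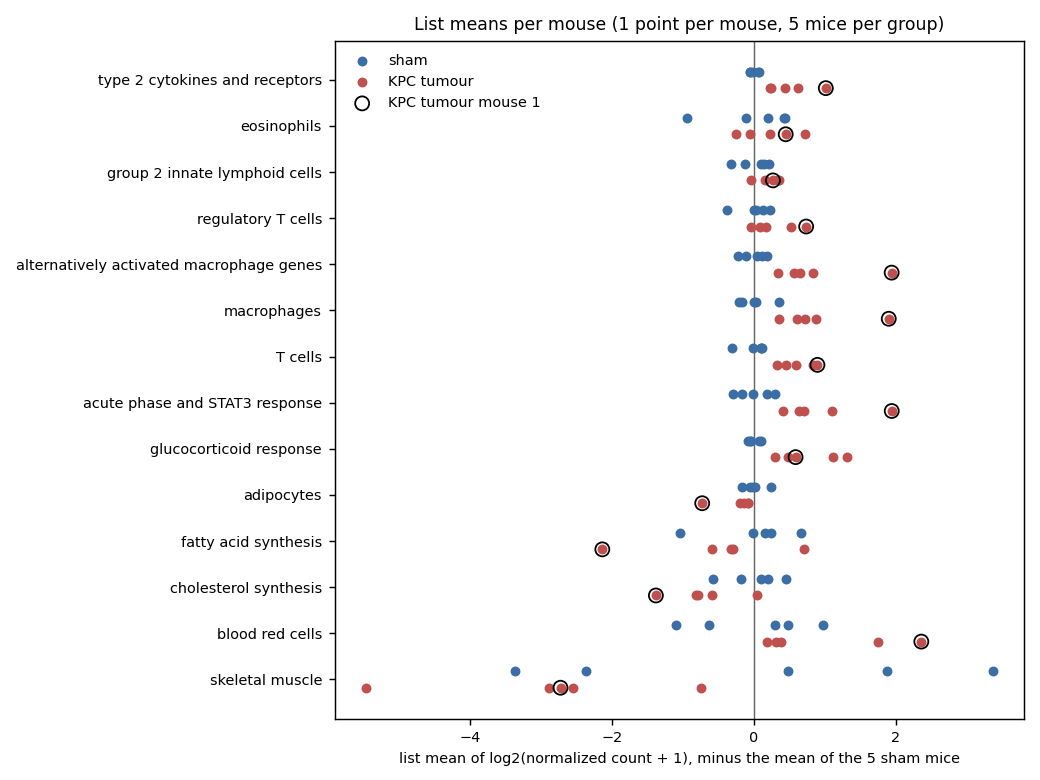
List mean of each mouse minus the mean of the 5 sham mice, on the x axis in log2 units, for 14 gene lists on the y axis; each point is 1 mouse, coloured by group, and a ring marks KPC tumour mouse 1. For the type 2 list the 5 KPC mice lie above the 5 sham mice, for eosinophil, innate lymphoid and regulatory T cell lists the groups overlap, and KPC mouse 1 is the farthest from sham for macrophages, at 1.90, and fatty acid synthesis, at -2.14.

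Over the 44 lists, 7 passed the exact permutation test, all higher, and 0 passed it lower, with 16 at an unadjusted exact p under 0.05. The adjusted p of 0.0499 lies just under the threshold: it rests on 7 lists sharing the smallest p that 5 mice against 5 can give, and the lists share members and mice. No list passed the exact test after leaving out KPC mouse 1 or any 1 sham mouse. Camera called 15 lists higher and 10 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.224. Fry, which tests whether the genes of a list move one way on balance, called the T cell, dendritic cell and acute phase lists, all higher, and its mixed test called 10 lists.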

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

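The search for single mice far from their group was set before the data were examined, and of the tests reported here the division of the mice into other groups was too, while the others were chosen after the results they bear on were seen. Over 242 groups of 5 mice (lists and named genes), 18 had 1 mouse whose gap to the nearest other was more than 0.71 of the group's range on the log2 scale. Chance gives about 1 in 20 groups, or 12.1 here, and 14 of the 18 were in KPC mouse 1.

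KPC mouse 1 had the highest list mean (log2 normalized count) of the KPC group for monocytes, 9.60 against 7.88 to 8.23 in the others, inflammatory cytokines and chemokines, 8.20 against 5.74 to 6.42, interferon response, 9.57 against 8.86 to 9.06, and cell cycle, 7.94 against 5.65 to 6.12. It had the lowest list mean for adipocytes, 13.67 against 14.20 to 14.31, triglyceride synthesis and fat uptake, 11.35 against 12.12 to 12.41, and insulin and glucose handling, 10.40 against 10.92 to 11.04. In normalized counts, it was highest for the chemokine gene Ccl8 at 14820 against 1476 to 2587, for the clotting factor gene F10 at 162 against 25.9 to 41.4, and for the granulocyte receptor gene Csf3r at 480 against 104 to 139.9. It was also highest for the antiviral gene Oas2 at 1031 against 258 to 356 and for the surface antigen gene Ly6a at 7587 against 4089 to 4482. It was lowest for the lipase genes Pnpla2, at 30190 against 47510 to 56710, and Lipe, at 20450 against 32020 to 35140.

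In other mice, Cebpd was lowest of the sham group in sham mouse 5, at 411 normalized counts against 679 to 798, and Oas2 was highest in sham mouse 1, at 293 against 117 to 133. The endoplasmic reticulum stress list was highest in sham mouse 2, at 10.70 against 10.50 to 10.55, and Cd163 was highest of the KPC group in KPC mouse 4, at 3824 against 2403 to 2721.

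KPC mouse 1 stood apart from the other 9 libraries. Fewer reads do not account for this, since its estimated 19030000 reads exceeded the lowest other library at 15700000. Dilution of adipocyte RNA alone was set to keep its fatty acid synthesis genes as low as its adipocyte genes, within the sham range. The log2 difference between these lists was -1.41 in KPC mouse 1, below the lowest sham mouse at -0.875. KPC mouse 3 left that range on the other side, at 0.898 where the highest sham mouse had 0.423. A single mouse outside the range therefore cannot decide on dilution. For KPC mouse 1 a further comparison was made. Its deviation from one part of the shams correlated across genes with that of the other 4 KPC mice from the remaining shams, with a median r of 0.323 where the highest sham mouse had 0.173, so a larger degree of the same change is a candidate explanation. KPC mouse 5 had 0.173 and KPC mouse 2 0.349 in the same test, genes are not independent replicates, and a further illness or a different piece of tissue in this mouse stays open.

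Macrophage genes lay higher in KPC mice. A lower share of muscle or adipocyte RNA would lift every other cell type alike, and macrophage genes exceeded the mean of endothelial and progenitor genes by 0.81 (exact permutation p = 0.00794, the smallest possible). Endothelial and progenitor genes had already been seen to differ by 0.09 and 0.06, so this p-value describes these data only. Blood in the tissue would not bring resident macrophage genes, and the mean of Folr2, Lyve1 and Timd4, which are not in the macrophage list, differed by 0.493 on the log2 scale (exact permutation p = 0.0238) and by 0.25 without KPC mouse 1 (exact permutation p = 0.0476). All 3 genes are in the alternatively activated list, whose rise had been seen, so these p-values describe these data only. Timd4 alone differed by 0.28 (limma unadjusted p = 0.242). The values argue, narrowly, against blood as the whole source, and blood as part of the higher macrophage, monocyte and T cell genes stays open. Blood together with a lower share of muscle or adipocyte RNA was not tested. More macrophages, or more of these transcripts in each, may account for the pattern, and bulk tissue does not separate them.

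Chance was weighed by dividing the 10 libraries into other groups of 5, with 100 divisions drawn. The real grouping called 8 genes and the highest other 2, so that 1 of 100, the real one, gave as many. Camera called 25 lists in the real grouping and 26 in the highest other, and 4 of 100 gave as many, the real one included. The division with 26 lists exchanged 2 mice of each group, and both others with as many as the real grouping exchanged 1. For both counts the share lay under the 0.05 set beforehand, narrowly for the lists, and no other drawn division called as many genes. Not all possible divisions were drawn, and another division called more lists than the real one. Chance is therefore not excluded for the list count.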

How the results depend on the processing

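The covariate, the joint removals of mice and the type 2 list without Ccl8 were chosen after the data were seen; the rest was planned. The planned count tests were not run, because whole reads were not recovered. No direction reversed for any called gene or list. Over all alternatives, 149 of 224 values of the 8 called genes kept their call and 75 lost it, and 44 of 4783 values of genes not called passed. Csf2rb2 kept its call in 26 of 28 alternatives, Cebpd in 24, Mt2 in 17, Ifi205 in 15, Ifi207 and Osmr in 14 each and Cyb561 in 13. Both joint removals left too few mice for the exact test of lists: with smallest possible p-values of 0.0286 and 0.0476, 26 and 42 of 44 lists at that p would be needed for a pass, so the calls lost there say nothing of stability. Over the other alternatives, 72 of 119 values of the 6 called lists apart from type 2 kept the call and 47 lost it, and 10 of 736 values of lists not called passed.

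Against 7 genes higher and 1 lower by limma, pseudocounts, other scalings, a robust fit and no filter gave 7 and 1, and a mean of at least 50 gave 8 and 1. TPM with a pseudocount of 0.1 gave 4 and 1, and with 1 gave 2 and 0. Array weights, which gave KPC mouse 1 a weight of 0.177 and the others 0.649 to 2.25, gave 172 and 28. Removal of the length trend gave 21 and 1, the skeletal muscle covariate 0 and 1, leaving out KPC mouse 1 and sham mouse 5 52 and 3, and leaving out sham mice 3 to 5 3 and 1, with 0 of the 8 genes among them. Leaving out 1 mouse in turn gave 1 to 66 higher and 1 to 4 lower. Apart from the smaller samples, the cause was not tested.

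Against 15 lists higher and 10 lower by camera, array weights gave 16 and 3 and leaving out KPC mouse 1 and sham mouse 5 gave 15 and 6. Leaving out 1 mouse gave 15 to 17 higher and 4 to 12 lower. An estimated correlation gave 0 and 0, fry 3 and 0 and the exact test 7 and 0. Against 7 lists by the exact test, there were 0 with no filter (smallest adjusted exact p = 0.0510), 0 with a mean of at least 50 (0.0516), and 0 without KPC mouse 1 and sham mouse 5 or without sham mice 3 to 5, where a pass was hardly possible. Leaving out 1 mouse gave 0 to 8, with 0 for each sham mouse and for KPC mouse 1. The exact test was not run with weights, blocks or covariates.

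The type 2 list difference of 0.51 was 0.39 with no filter (adjusted exact p = 0.143), 0.60 with a mean of at least 50 (0.0516), 0.40 without KPC mouse 1 and sham mouse 5 and 0.54 without sham mice 3 to 5, and 0.30 without Ccl8 (0.116). Leaving out 1 mouse gave 0.38 to 0.58. Its adjusted exact p ranged from 0.0349 to 0.143 over the 21 alternatives apart from the joint removals, and the cause was not tested.

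The numbers 1 to 5 in the labels are not shown to pair the mice, and 5 pairs are too few to exclude a weak pairing. Deviations of same-numbered mice correlated at 0.068, 0.191, 0.00505, 0.02 and 0.171, all above 0, and 2 of 5 mice correlated best with their own number. With that number as a replicate block, limma called 3 genes higher and 1 lower, and with the length trend removed as well 3 and 1. The first number of the title as a block gave 3 and 1, the labels do not say whether it marks a cage, litter or batch, and same-numbered pairs there correlated at 0.0653 on average where others had -0.0294.

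Depth limits the low genes: Il5, Il13 and Ifng were seen only in the TPM table, and the estimated 15700000 reads of the shallowest library leave changes at such levels undetectable here.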

Other observations

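The gene lists of this part (MHC class I pathway, p200 family, Fc gamma receptors and venule adhesion molecules) and the test of type 2 members were chosen after the values were seen, on the same mice. The lists are therefore given as values without a test, and the p-values of the type 2 members describe these data only.

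Genes that present antigen to cytotoxic T cells, those of the MHC class I pathway, differed by 0.47 in list mean over 18 genes, 17 of them positive. The class I chain gene H2-K1 stood at 799 ± 127 against 1124 ± 144 TPM and the immunoproteasome gene Psmb8 at 50.2 ± 6.88 against 89.1 ± 20.8 TPM, while Tapbp, which loads peptides, stood at 36.2 ± 3.31 against 34.1 ± 5.46 TPM. Class I genes are near copies of each other, so their single levels are uncertain.

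The p200 family of interferon-inducible genes, which holds the called genes Ifi205 and Ifi207, differed by 0.98 over 11 genes, all positive. Ifi204 stood at 26.2 ± 1.41 against 47.9 ± 20.1 TPM and Ifi211 at 19.6 ± 2.43 against 42.1 ± 19.1 TPM. Fc gamma receptor genes, through which macrophages bind antibody, differed by 1.54 over 5 genes, with Fcgr2b at 28.9 ± 3.36 against 90.5 ± 51.6 TPM and Fcgr4 at 1.52 ± 0.235 against 11.4 ± 12.1 TPM, or 5.99 TPM in KPC mice without KPC mouse 1. Adhesion molecules of venules that recruit leukocytes differed by 1.12 over 5 genes. The selectin genes Sele and Selp stood at 0.251 ± 0.0729 against 1.22 ± 0.556 TPM and 4.72 ± 0.997 against 11.7 ± 4.21 TPM and Ackr1, a chemokine-binding protein of venules, at 13.1 ± 1.83 against 23.9 ± 4.45 TPM.

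A hypothesis for the type 2 list is that it lay higher through members outside the lists of eosinophils, group 2 innate lymphoid cells and regulatory T cells. The 9 members outside, among them Il33, Ccl8, Ccl11 and Il4ra, differed by 0.62 (95% interval 0.26 to 1.08, exact permutation p = 0.00794), and the 4 inside, Il1rl1, Il17rb, Il2ra and Gata3, by 0.25 (95% interval -0.10 to 0.69, exact permutation p = 0.198). The difference between the parts was 0.368 (95% interval -0.22 to 1.15, exact permutation p = 0.286), and it rested on Ccl8. Without that gene the 8 members outside differed by 0.33 (95% interval -0.005 to 0.75, exact permutation p = 0.0556), and the difference between the parts was 0.08 (95% interval -0.49 to 0.75, exact permutation p = 0.857). A p of at least 0.05 had been set to count against the hypothesis, but both intervals run from below 0 to above the difference of the whole list, so the parts are not shown to differ and the question stays open.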
